A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

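The measurement was a growth selection in budding yeast. Short pieces of yeast cDNA were joined to the end of a Ura3-HA-GFP reporter gene in any of 3 reading frames, per the labels' protocols, and pooled cells were kept in medium with 5-fluoroorotic acid. That compound is turned into a toxin by Ura3, so cells whose reporter protein is low are favoured. At each time the plasmid inserts were amplified and sequenced, and the share of reads of an insert follows the share of cells that carry it.

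The deposited table gives whole-number read counts per insert and library, with the insert's chromosome, start, end, strand and reporter frame. Per the submitters' processing notes, bcl2fastq, Bowtie2 and the sacCer3 build were used. How reads were turned into counts and how reads that map to several places were treated is not given in the sources used here. The table holds 142830 fragments. Every library has count columns under the prefix a, and all but 1 also have a column under the prefix p, whose difference in meaning is not given in the sources used here. The a columns were used throughout because they are deeper and cover all libraries, and the p columns served as an alternative chosen after the data were seen. The number of count columns that matched no sample is 1, and it was not used.

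The labels give 3 arms, each grown in a single flask. The cytosolic arm carried the reporter plasmid labelled cytosolic and was sampled at 0, 12, 24, 48 and 72 h. The nuclear arm carried the plasmid labelled nuclear and was sampled at the same times. The doa10 arm carried the cytosolic plasmid in cells lacking DOA10 and was sampled at 0, 30, 46, 64, 72, 78, 90 and 96 h. Each arm and time has 1 library, so there are no replicates. P-values rest on the spread of the time points of 1 flask around a line, and a difference between arms is also a difference between flasks. The test shares that spread between fragments. The prior degrees of freedom of this sharing were infinite for the cytosolic trend, the nuclear trend and the doa10 against cytosolic difference. There the p-value and standard error of a fragment come from the spread pooled over fragments, not from its own. The prior degrees of freedom were 2.589 for the doa10 trend and 52.86 for nuclear against cytosolic.

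Source genes were assigned by overlap of the part of the insert that encodes the tail with the coding genes of the R64 RefSeq table, and the strand was read from the systematic name. The table holds 6021 coding genes, of which 6002 have a strand, and 107549 fragments from 5453 genes were matched. For 3562 fragments the insert is not resolved in the table, and 10609 fragments share their sequence with at least 1 other. Tails were translated from the fusion junction to the next stop or, where the insert held none, to the end of the insert. Vector bases after the insert were not read, so the length of a tail without a stop is a lower bound. Tails counted as under 5 residues can thus include short inserts whose tail goes on. Of inserts of at least 60 nt, 28.7% held a stop in the native frame, 95.3% in another sense frame and 90.3% antisense. A fragment was called native when it lay on the sense strand in the frame of the annotated stop codon. Introns were not considered, so the frame and tail of a fragment that spans or precedes an intron are uncertain, as are those of inserts much longer than the sequenced range. A fragment was called a near-duplicate when it shared an end with a fragment of at least 10 times its reads and the other end lay within 15 bases. These make 55839 fragments and 0.460% of reads.

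The trend of each fragment was tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F test, with time in days as a number, library totals as the scaling and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. The slope is the change of the log2 share of reads per day, and values after ± are its standard error. Fragments with a mean of at least 10 reads per library of the fit were tested. The slope of a fragment that reaches 0 reads depends on the prior count of the model and is not a bound. Differences between arms were tested as the interaction of arm and time over the libraries of the pair. DESeq2 1.42.0 with its Wald test was an alternative. Gene lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry from limma 3.58.1, and each list median was set against 10000 random fragment sets matched on mean count. Tail features were summarised in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Intervals of feature values are 95% intervals from 1000 bootstrap draws of source genes, or of 10000-base blocks where no gene was given. The fragments behind a rho are not independent replicates. Intervals of read shares are 95% Wilson intervals. The reads are PCR products without molecular identifiers, so these intervals, and the share that a count of 0 allows (3 reads of the total), cover counting error only.

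The designs, the gene lists, the tail features and the rule for named fragments were fixed before the data were examined. By that rule, the fragments named for each trend are the 10 largest rises and the 5 largest falls among calls with at least 1000 reads over the fit, and the 5 most abundant at 0 h. For each difference they are the 10 largest in each direction under the same minimum. At most 1 fragment per gene was taken, and fragments without a gene are named by position and strand. Each gene list adds up to 3 native-frame fragments with the smallest p in the cytosolic trend, and fragments of the list of short-lived or degron-studied proteins may be named from 100 reads. The leading fragments of the last time points, and the differences among fragments with at least 10 reads per library in each arm, were named after their values were seen. Some results that the rule names are not reported here. The lists are ribosomal proteins, glycolysis, plasma membrane transporters, endoplasmic reticulum membrane proteins, mitochondrial oxidative phosphorylation, cytosolic chaperones, proteasome, translation factors, histones, cell wall and secreted proteins, nucleolar ribosome biogenesis, and short-lived or degron-studied proteins. Some symbols were not in the gene table, most of all for oxidative phosphorylation, where 26 of 36 were found.

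The fits were tested on simulated data drawn from the means and totals of the real libraries. In each fit 68, 66 and 66 fragments were changed by 1, 2 and 4 log2 units per day, up or down, and the others were left flat. In the real trends most fragments were called. The adjusted cutoff therefore differs, and the rates below do not measure detection in the real trends. A slope of 4 log2 units per day was called for 95.5% of changed fragments in the cytosolic arm, 89.4% in the nuclear arm and 92.4% in the doa10 arm. A slope of 2 was called for 39.4%, 25.8% and 74.2%, and a slope of 1 for 1.47%, 2.94% and 17.6%. For the differences between arms, 4 units per day were called for 30.3% (nuclear minus cytosolic) and 47.0% (doa10 minus cytosolic), 2 units for 0% and 6.06%, and 1 unit for 0% in both. The alternatives were TMM and median-of-ratios scaling, no filter on low counts, a minimum of 50 reads, leaving out each library, a joint fit of all libraries, the rank of time in place of hours, doa10 times up to 72 h only, a ratio of 72 h over 0 h, other pseudocounts, 1 fragment per gene, and native-frame fragments only. The p columns, the omission of near-duplicates, unique resolved inserts, single reporter frames, a minimum in each arm and a block per time point for the nuclear and cytosolic arms were added after the data were seen. The deletion of DOA10, which the gene table lists as SSM4 (YIL030C), is not measured by insert counts, so the label of that arm has no check of its own.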

Results

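The series follows pools of yeast cells that carry a Ura3-HA-GFP reporter with a peptide tail encoded by a piece of yeast cDNA, grown in 5-fluoroorotic acid, which kills cells with an active Ura3 protein. A tail that lowers the reporter is therefore expected to gain share over time, and the read count of each cDNA insert was measured in 18 libraries. The cytosolic arm has 5 libraries from 0 to 72 h, with totals from 10697560 reads at 0 h through 7095997 at 12 h, 3317754 at 24 h and 1002391 at 48 h to 576317 at 72 h. The nuclear arm has 5 libraries at the same times, with 8943457 reads at 0 h, 8054885 at 12 h, 9063 at 24 h, 2619302 at 48 h and 2405096 at 72 h. The arm lacking DOA10, a ubiquitin ligase of the endoplasmic reticulum and the inner nuclear membrane, carried the cytosolic plasmid and has 8 libraries from 0 to 96 h, with 840381, 616053, 371823, 223739, 248029, 263948, 172186 and 162927 reads in order of time. Each arm is a single flask with 1 library per time and no replicates. A count of 0 allows a share of up to 0.000521% at 72 h in the cytosolic arm, 0.000125% in the nuclear arm and 0.00121% in the doa10 arm. Of the fragments with a resolved insert, 16859 lay on the sense strand of a gene in its native frame and 34365 in another frame. Another 53909 lay antisense to a gene and 34135 outside the annotated coding spans. The median insert was 197 nt long. A fragment that is antisense or in another frame is named after the gene it comes from, and its tail is unrelated to that gene's protein.

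In the cytosolic arm the question was which tails gain or lose share under selection with the cytosolic reporter. A native-frame fragment of RPS8A (YBL072C, chromosome 2, 88670 to 89015, sacCer3), which encodes a protein of the small ribosomal subunit, rose from 0.0264% of reads (95% interval 0.0255 to 0.0274) to 17.2% (17.1 to 17.3), at 2.85 ± 0.12 log2 units per day. An antisense fragment of RPL12A (YEL054C, chromosome 5, 53027 to 53203), a gene for a protein of the large subunit, encodes the 6-residue tail GSLIGR and rose from 0.0613% to 8.69% (2.56 ± 0.14). A fragment of IDP1 (YDL066W, chromosome 4, 335614 to 336045), the gene of a mitochondrial isocitrate dehydrogenase, encodes the tail RDPL in another frame and rose from 0.000682% to 1.06% (3.39 ± 0.38). Most of the pool lost share: of 10796 fragments tested, 288 rose and 6996 fell, and the median slope was -1.99. The rising fragments came from 194 genes and 276 start sites and held 4.23% of reads at 0 h and 78.4% at 72 h. The edgeR quasi-likelihood test gave the RPS8A fragment an adjusted p of 8.47e-123, which rests on the spread pooled over all fragments and not on its own time points. The scaling and the tool moved the split of calls: TMM gave 266 rises and 238 falls (median slope -1.10), size factors 624 and 4693 (-1.51) and DESeq2, which also changes the test, 700 and 4761 (-1.21). Single libraries also moved the counts, with 191 rises without the 0 h library, 44 rises and 501 falls without 12 h, and 10 rises and 0 falls by edgeR without 72 h, where 380 rose and 3879 fell at an unadjusted p under 0.05.

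The largest rises by the naming rule were those of a near-duplicate of the RPS8A fragment (chromosome 2, 88670 to 89006, 3.49 ± 0.75) and of SSE1 (YPL106C, antisense, chromosome 16, 350312 to 350887, 3.47 ± 0.62), whose protein is an Hsp110 chaperone. IDP1 came next, with RPL16B (YNL069C, other frame, chromosome 14, 493932 to 494068, 3.38 ± 0.51) and POL32 (YJR043C, 3.37 ± 0.89). Fragments of YJL132W (3.36 ± 0.77), MTC1 (YJL123C, 3.36 ± 0.60) and SAC6 (YDR129C, 3.31 ± 0.54) rose at like rates. The rule also named HTZ1 (YOL012C, antisense, chromosome 15, 303740 to 303826, 3.27 ± 0.60), the gene of the histone variant H2A.Z, and ARO7 (YPR060C, 3.16 ± 0.42). The steepest falls were those of RAP1 (YNL216W, antisense, chromosome 14, 243121 to 243183, -6.99 ± 1.73), which codes for a protein that binds telomeres and promoters, and AGP1 (YCL025C, an amino acid permease gene, -6.48 ± 1.57). RPS1A (YLR441C, -6.11 ± 1.49), TEA1 (YOR337W, -5.39 ± 1.39) and UBC4 (YBR082C, a ubiquitin-conjugating enzyme gene, -5.30 ± 1.35) followed. These 5 fragments had 0 reads at 48 and 72 h. The most abundant fragment at 0 h, on the plus strand of chromosome 4 from 130300 to 130417 with no gene, rose at 0.62 ± 0.18 (-0.60 in the p columns). The same insert on the minus strand, from RPL41A (YDL184C), had a slope of -0.10 ± 0.25, and RPL38 (YLR325C) in its native frame had -0.40 ± 0.34. RPL41B (YDL133C-A, antisense) had 0.58 ± 0.27, and the plus strand of chromosome 15 from 1028154 to 1028221 had -1.33 ± 0.50. Antisense fragments of RPL1B (YGL135W, chromosome 7, 254237 to 254652) rose at 1.96 ± 0.23 to 2.01% at 72 h. An insert shared by RPL9A (YGL147C) and RPL9B (YNL067W), antisense in both, rose at 1.77 ± 0.24 and 1.79 ± 0.24, and its split between these near-identical copies is uncertain.

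**Figure D1:**
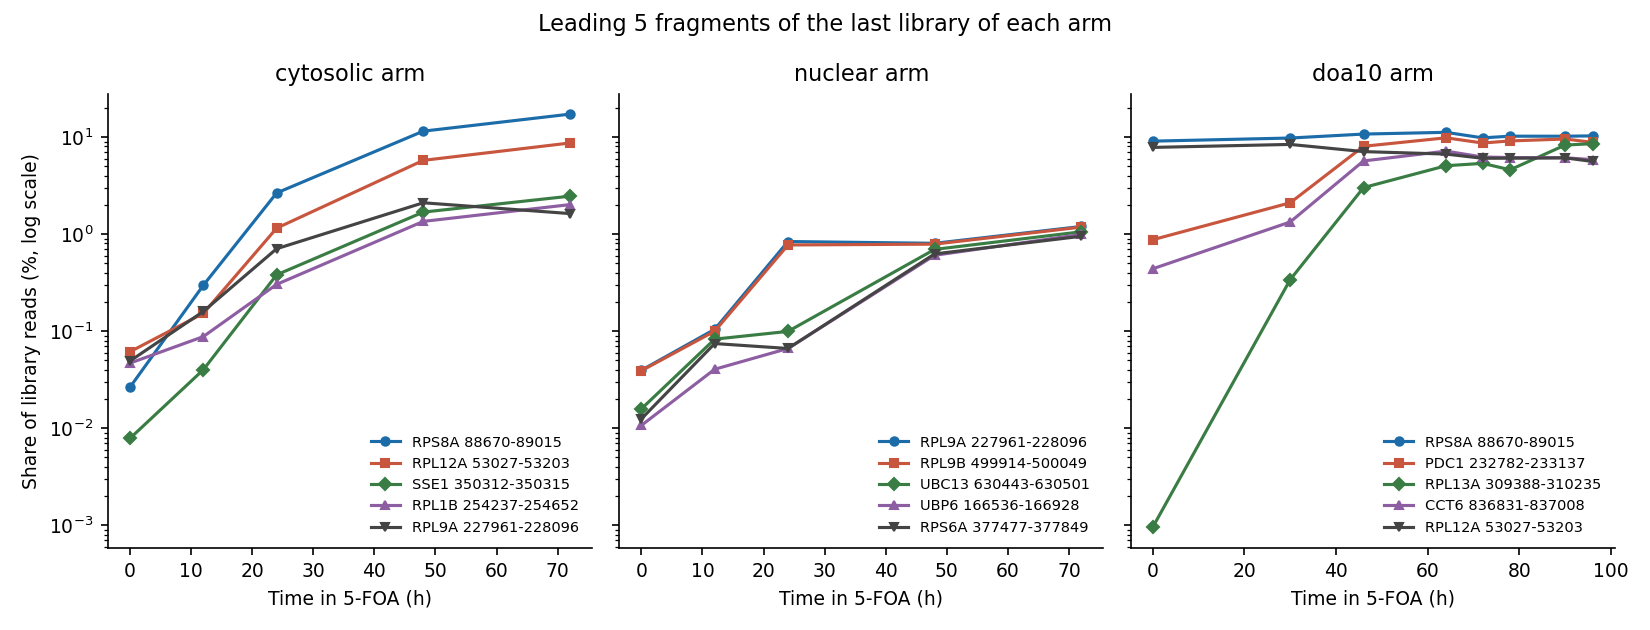
Share of library reads (percent, log axis) against time in 5-fluoroorotic acid (h) for the 5 fragments that led the last library of each arm, with 1 line per fragment, a panel per arm, and times without reads left out. RPS8A led the cytosolic arm with 17.2% at 72 h and the doa10 arm with 10.3% at 96 h, and RPL9A led the nuclear arm with 1.20% at 72 h.

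Among the gene lists in the cytosolic arm, ribosomal protein genes gave 1074 tested fragments from 111 genes, of which 58 rose and 602 fell (56 and 582 adjusted over the list alone), and their median of -1.80 lay at percentile 100 of the matched random sets. Glycolysis gave 7 rises and 150 falls of 266 (7 and 142 over the list alone, median -1.70, percentile 99.5). A native-frame fragment of FBA1 (YKL060C, fructose-bisphosphate aldolase, chromosome 11, 326129 to 326453) rose at 1.29 ± 0.33 (-1.42 in the p columns), and those of TDH1 (YJL052W, -4.51 ± 1.18) and GPM1 (YKL152C, -2.54 ± 0.68) fell. Mitochondrial oxidative phosphorylation gave 0 rises and 39 falls of 50 by edgeR (0 and 42 over the list alone, median -2.55, percentile 0.54). Native-frame falls were those of ATP7 (YKL016C, -2.88 ± 0.82), PET9 (YBL030C, -2.85 ± 0.92) and ATP2 (YJR121W, -2.29 ± 1.02). Plasma membrane transporters gave 3 rises and 60 falls of 81 (3 and 61 over the list alone, median -2.44, percentile 2.70). Falls were those of native-frame AGP1 (chromosome 3, 75712 to 76141, -5.03 ± 1.22) and PMA1 (YGL008C, the plasma membrane proton pump, -2.37 ± 0.76). Endoplasmic reticulum membrane proteins gave 3 and 75 of 109 (3 and 75), with falls of SEC61 (YLR378C, the translocon channel, -3.75 ± 1.06) and ERG11 (YHR007C, chromosome 8, 121052 to 121585, -3.00 ± 0.88). Cytosolic chaperones gave 10 and 95 of 168 (10 and 93), with native-frame falls of CCT6 (YDR188W, chromosome 4, 836768 to 836834, -3.17 ± 0.89), SSA2 (YLL024C, -3.42 ± 0.98) and SSE1 (chromosome 16, 350162 to 350315, -3.65 ± 1.09). With TMM the rises and falls were 53 and 8 for ribosomal proteins, 8 and 1 for glycolysis and 0 and 1 for oxidative phosphorylation. They were 2 and 4 for plasma membrane transporters, 3 and 3 for endoplasmic reticulum membrane proteins and 9 and 6 for chaperones.

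The proteasome list gave 0 rises and 66 falls of 102 by edgeR (0 and 65 over the list alone), among them native-frame fragments of RPN2 (YIL075C, -4.74 ± 1.20), RPN6 (YDL097C, -3.71 ± 0.97) and PRE3 (YJL001W, -3.87 ± 1.02). Translation factors gave 4 rises and 115 falls of 192 (3 and 113), with falls of TIF34 (YMR146C, -4.68 ± 1.19) and EFT1 (YOR133W, elongation factor 2, chromosome 15, 577142 to 577261, -2.56 ± 0.79). Histones gave 1 and 34 of 48 (1 and 34), with falls of HHT1 (YBR010W, -3.93 ± 1.17), HHF2 (YNL030W, -2.73 ± 0.85) and HHT2 (YNL031C, -1.54 ± 0.63). Cell wall and secreted proteins gave 1 and 53 of 75 (1 and 54), with falls of SCW4 (YGR279C, -3.00 ± 0.83), TIR1 (YER011W, -3.62 ± 1.07) and SCW10 (YMR305C, -2.68 ± 0.83). With TMM the rises and falls were 0 and 2 for the proteasome and 3 and 8 for translation factors. They were 1 and 1 for histones and 1 and 2 for cell wall and secreted proteins. Nucleolar ribosome biogenesis gave 2 and 38 of 70 (2 and 38), with falls of NSR1 (YGR159C, chromosome 7, 806897 to 807037, -4.28 ± 1.14) and GAR1 (YHR089C, -3.77 ± 1.04). Short-lived or degron-studied proteins gave 2 and 20 of 28 (2 and 21). The rises were an antisense fragment of GCN4 (YEL009C, the activator of amino acid synthesis genes, chromosome 5, 139601 to 140136, 1.55 ± 0.60) and a fragment of SIC1 (YLR079W, a cyclin-dependent kinase inhibitor, chromosome 12, 287660 to 288126, 1.84 ± 0.64) in another frame. The native-frame fragment of CLN2 (YPL256C, a G1 cyclin, chromosome 16, 65534 to 65832) fell by 3.62 ± 1.21 and that of GCN4 (chromosome 5, 139085 to 139163) by 2.22 ± 0.86. No list stood apart from the other fragments in limma's camera, where the smallest adjusted p was 0.378 (adjusted p = 0.989 with an estimated correlation). The fry test, which asks whether a list moves on balance one way, gave falls for all 12 lists (adjusted p 0.00591 to 0.0112). With library totals as the scaling, 64.8% of all tested fragments fell in the cytosolic arm, 67.6% in the nuclear and 62.6% in the doa10 arm. In any arm a fall by fry therefore follows the pool and does not set a list apart. With TMM the fry call was lost for ribosomal proteins (adjusted p 0.0544) and glycolysis (0.0923) and kept for the other lists. The direction in camera against other fragments was upward for ribosomal proteins, glycolysis, chaperones and translation factors.

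Tails of 20 or more residues rose in 2.77% of 4110 fragments and tails under 5 residues, which serve as the near-empty background, in 2.39% of 1587, a difference of 0.379 points (95% interval -0.504 to 1.23). That difference was 0.780 points (0.0123 to 1.55) without near-duplicates, 1.61 points (0.108 to 3.09) in reporter frame 2, -1.25 points (-2.94 to 0.189) in frame 0 and -3.07 points (-6.70 to -0.285) in the p columns. Across fragments, the slope had a Spearman rho of 0.0236 with tail length. For length it was 0.0843 (0.0474 to 0.119) with 1 fragment per gene and 0.0512 (0.0206 to 0.0834) in frame 1. It was -0.0182 in frame 0, -0.0231 in frame 2 and -0.00519 for the 72 h over 0 h ratio. The rho was 0.0299 (0.00574 to 0.0531) with the most hydrophobic 9 residues and 0.112 (0.0936 to 0.131) with the share of acidic residues, of 8 features examined in each arm. Mean hydropathy had the opposite sign (-0.0274, -0.0468 to -0.00737). The value for the 9 residues turned to -0.0225 in frame 1, and its interval reached 0 in frame 0 and for the 72 h over 0 h ratio. Leucine made up 11.8% of the residues of rising tails and 10.2% of other tails. Fragments in the native frame rose in 3.05% of 1313 cases, antisense fragments in 3.12% of 4580, fragments in another sense frame in 2.40% of 2873 and those outside coding spans in 1.80% of 1889. Reporter frames 0, 1 and 2 gave rises in 1.72%, 2.83% and 3.75%. The vector and the cut site start nearly all tails with GS in frame 0, RI in frame 1 and RD in frame 2. Nearly every frame 2 tail therefore holds an aspartate. The share of acidic residues was not examined within a frame, so in any arm its rho cannot be told apart from the mix of frames.

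In the nuclear arm the same question was asked with the nuclear reporter. The largest rises by the rule were those of YLH47 (YPR125W, a mitochondrial inner membrane protein gene, antisense, chromosome 16, 787811 to 788816, 3.48 ± 0.66), and ESC1 (YMR219W, other frame, chromosome 13, 709866 to 709974, 3.17 ± 0.59). RIB3 (YDR487C, a riboflavin synthesis gene, other frame, chromosome 4, 1428078 to 1428393) rose at 3.09 ± 0.55, and RRN5 (YLR141W, a gene of the RNA polymerase I machinery, antisense, chromosome 12, 424455 to 424731) at 3.05 ± 0.56. They were followed by antisense fragments of TAF3 (YPL011C, a TFIID subunit gene, 2.89 ± 0.55), ASK1 (YKL052C, a kinetochore gene, 2.86 ± 0.56) and AUS1 (YOR011W, a sterol transporter gene, 2.79 ± 0.58). The remaining named rises, also antisense, were those of GPN3 (YLR243W, 2.76 ± 0.67), VMA7 (YGR020C, a vacuolar ATPase gene, 2.64 ± 0.55) and SEC6 (YIL068C, an exocyst gene, 2.63 ± 0.68). Of 14035 fragments tested, 858 from 566 genes rose and 9489 fell, with a median slope of -2.23. The pool stayed more even than the cytosolic pool, with 9.65% of reads on the 10 leading fragments at 72 h against 39.1%. By the edgeR test UBP6 had an adjusted p of 2.41e-05 in the nuclear arm, and its difference from the cytosolic arm (1.64 ± 0.63) had an adjusted p of 0.106. The scaling and the tool moved the split to 1624 rises and 6230 falls with TMM (median slope -1.33), 1336 and 7815 with size factors (-1.65) and 1440 and 5435 with DESeq2, which also changes the test (-1.66). There were 144 rises without the 0 h library and 259 without 12 h. The 24 h library held 9063 reads and leaned to fragments of the cytosolic arm, and without it 876 rose and 9702 fell and the tail excess was 4.61 points.

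The leaders at 72 h were the RPL9A and RPL9B insert with 1.20% and 1.18% of reads (1.39 ± 0.44 and 1.42 ± 0.44, split uncertain). An antisense fragment of UBC13 (YDR092W, chromosome 4, 630443 to 630501), the gene of a ubiquitin-conjugating enzyme of DNA repair, had 1.06% (1.97 ± 0.43). A native-frame fragment of UBP6 (YFR010W, chromosome 6, 166536 to 166928), a deubiquitinase of the proteasome, had 0.992% (95% interval 0.980 to 1.005) and a slope of 2.28 ± 0.44, and an antisense fragment of RPS6A (YPL090C, chromosome 16, 377477 to 377849) had 0.949% (2.02 ± 0.43). The steepest falls were those of ADE2 (YOR128C, an adenine synthesis gene, other frame, -5.99 ± 1.04) and CHS5 (YLR330W, native frame, chromosome 12, 788207 to 788321, -5.95 ± 1.06). ERO1 (YML130C, the endoplasmic reticulum oxidase gene, antisense, -5.88 ± 1.05), CTR9 (YOL145C, -5.86 ± 1.07) and TED1 (YIL039W, -5.79 ± 1.07) followed. The insert on chromosome 4 from 130300 to 130417 was again the most abundant at 0 h, and on its plus strand its share fell by 1.18 ± 0.52.

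Among the lists in the nuclear arm, ribosomal proteins gave 94 rises and 663 falls of 1189 fragments (88 and 648 adjusted over the list alone, median -1.33, percentile 100). Glycolysis gave 21 and 135 of 292 (17 and 126, median -0.96). Histones gave 10 and 43 of 70 (10 and 43), with a rise of native-frame HHF2 (1.19 ± 0.47). Nucleolar ribosome biogenesis gave 10 and 85 of 120 (10 and 85), with rises of native-frame NSR1 (chromosome 7, 806897 to 807037, 1.83 ± 0.64) and GAR1 (1.39 ± 0.56). Plasma membrane transporters gave 14 and 87 of 135 (14 and 87), endoplasmic reticulum membrane proteins 7 and 103 of 136 (7 and 103, median -2.69), and oxidative phosphorylation 12 and 59 of 80 (12 and 59). Chaperones gave 12 and 130 of 196 (12 and 130), and the proteasome 8 and 107 of 148 (8 and 107, median -2.78, percentile 0.53). Translation factors gave 13 and 137 of 233 (13 and 137), cell wall and secreted proteins 8 and 74 of 103 (8 and 74), and short-lived or degron-studied proteins 2 and 29 of 38 (2 and 29). The latter rises were an antisense fragment of CLN3 (YAL040C, a G1 cyclin gene, chromosome 1, 66641 to 66711, 1.65 ± 0.60) and an insert of GCN4 (chromosome 5, 139085 to 139163) in another frame (1.38 ± 0.48), whose native frame had a slope of 0.14 ± 0.43. In limma's camera the smallest adjusted p was 0.338 (0.997 with an estimated correlation), and fry gave falls for all 12 lists (adjusted p 0.00648 to 0.00689). With TMM 9 of the 12 fry calls were lost, among them ribosomal proteins (adjusted p 0.247), glycolysis (0.723), histones (0.183) and translation factors (0.144). Those of endoplasmic reticulum membrane proteins, cell wall and secreted proteins and nucleolar ribosome biogenesis stayed (0.0446).

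In the nuclear arm the slope varied more with tail length and hydrophobicity than in the cytosolic arm, but less with acidic residues (rho -0.0399 against 0.112). The share of rising fragments was 4.01% for tails under 5 residues, 3.12% for 5 to 9, 5.73% for 10 to 19, 8.17% for 20 to 49 and 10.2% for 50 or more, and tails of 20 or more residues exceeded the near-empty background by 4.64 points (95% interval 3.43 to 5.71). That excess was 7.34 points (5.85 to 8.85) with TMM, 7.68 (6.26 to 9.01) with DESeq2 and 7.53 (5.09 to 9.89) in the p columns. In reporter frame 0 it was 3.88 points (1.73 to 5.85). In the quintile of tails with the most hydrophobic 9 residues 11.3% rose, and in the lowest quintile 4.78%. The Spearman correlation across fragments was 0.155 (0.134 to 0.175) with that window, 0.135 (0.117 to 0.152) with tail length and 0.145 (0.121 to 0.168) with the hydropathy of the last 10 residues. Tails ending in alanine rose in 12.1% of 307 cases, in leucine in 8.84% of 1007 and in glutamate in 1.87% of 374. Rising tails held 2.01 points more leucine (1.41 to 2.61), and their aspartate content was -1.44 points relative to other tails (-1.78 to -1.09). Antisense fragments rose in 7.56% of 6360 cases, fragments in another sense frame in 6.36% of 3661, native-frame fragments in 4.25% of 1670 and those outside coding spans in 2.94% of 2212.

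**Figure D2:**
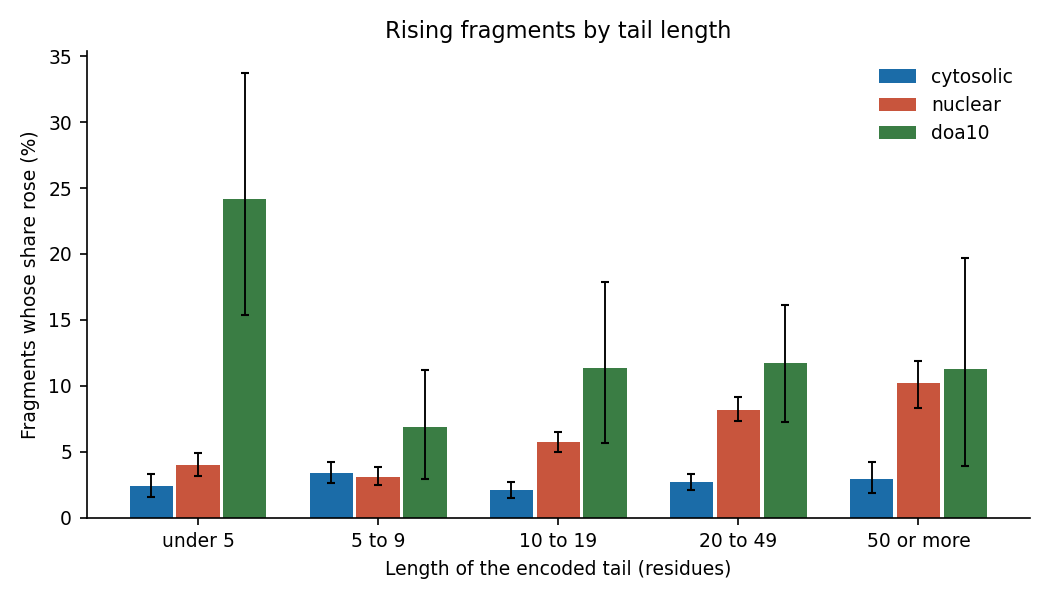
Percent of tested fragments whose share rose, by length of the encoded tail in residues, for the cytosolic, nuclear and doa10 arms, with 95% bootstrap intervals as error bars. The nuclear share climbs from 3.12% at 5 to 9 residues to 10.2% at 50 or more, the cytosolic share stays between 2.11% and 3.38%, and the doa10 share is 24.1% under 5 residues.

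In the doa10 arm the question was which tails gain or lose share when this ubiquitin ligase is missing. Its pool was already narrow at 0 h, with 35.6% of reads on 10 fragments against 2.84% in the cytosolic arm. The native-frame fragment of RPS8A (chromosome 2, 88670 to 89015) held 9.08% of reads (9.02 to 9.14) at 0 h and 9.82% (9.70 to 9.94) at 72 h, with a slope of 0.04 ± 0.04. Antisense RPL12A fell from 7.83% to 6.05% at 72 h (-0.14 ± 0.04), which turned to 0.40 with TMM and 0.18 with size factors or DESeq2. A fragment of RPL13A (YDL082W, a large-subunit gene, chromosome 4, 309388 to 310235) rose from 8 reads at 0 h to 8.55% of reads at 96 h (2.08 ± 0.69). Antisense PDC1 (YLR044C, pyruvate decarboxylase, chromosome 12, 232782 to 233137) rose from 0.875% to 8.83% at 96 h (0.84 ± 0.20). A fragment of CCT6 (a subunit of the TRiC chaperonin, chromosome 4, 836831 to 837008, plus strand, other frame) rose from 0.439% to 5.86% (0.91 ± 0.25). Of 605 fragments tested, 74 from 60 genes rose and 379 fell, and the median slope was -1.60. The edgeR test gave PDC1 an adjusted p of 0.00691 in the doa10 arm. The split was 109 rises and 268 falls with TMM (median slope -1.05), 110 and 324 with size factors (-1.29) and 129 and 289 with DESeq2 (-1.28), with 16 rises and 202 falls without the 0 h library and 48 rises without 30 h. With times up to 72 h only, edgeR called 0 rises and 0 falls (63 and 266 at an unadjusted p under 0.05).

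Other rises by the rule were those of the minus strand of chromosome 12 from 1029646 to 1029843 (2.24 ± 0.70), FRE3 (YOR381W, 2.16 ± 0.70) and YDR524W-C (antisense, 2.10 ± 0.62), which went from 30 to 8659 reads. ARC1 (YGL105W, 2.09 ± 0.77) and PDC5 (YLR134W, 1.15 ± 0.45) followed. Then came RPL28 (YGL103W, antisense, chromosome 7, 311810 to 311921, 1.11 ± 0.21) and ARO8 (YGL202W, an aminotransferase gene, antisense, chromosome 7, 116046 to 116161, 1.04 ± 0.23). The steepest falls were those of the minus strand of chromosome 15 from 220336 to 220509 (-5.28 ± 1.07) and ENA2 (YDR039C, a sodium pump gene with near-identical copies, so uncertain, -4.64 ± 0.97). SSA1 (YAL005C, an Hsp70 gene, antisense, -4.33 ± 0.69), the Ty element YGR038C-B (uncertain for the same reason, -4.31 ± 0.82) and native-frame PHS1 (YJL097W, a dehydratase of fatty acid elongation, chromosome 10, 246216 to 246785, -4.20 ± 0.92) followed. The largest rises of the cytosolic arm included IDP1, which fell here by 4.00 ± 0.80, and HTZ1, which fell by 3.12 ± 0.59. Of 132 fragments that rose in the cytosolic arm and were tested here, 5 rose, 80 fell and 47 were not called. The falls were 60.6% of them, against 70.8% of the 120 fragments that fell in the cytosolic arm. Independent lists would share 6.97 rises (Fisher's exact test, two-sided p = 0.499).

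Among the lists in the doa10 arm, ribosomal proteins gave 10 rises and 93 falls of 148 (9 and 91 adjusted over the list alone, median -0.96, percentile 93.2), with RPL13A and RPL28 among the rises. Glycolysis gave 5 and 31 of 50 (5 and 31), with rises of PDC1 and PDC5 and a fall of native-frame FBA1 (-0.49 ± 0.13). Chaperones gave 1 and 13 of 17 (1 and 13), nucleolar ribosome biogenesis 1 and 2 of 5 (1 and 2), translation factors 0 and 5 of 11 (0 and 5) and histones 0 and 4 of 6 (0 and 4). The fragments of plasma membrane transporters (0 and 2), endoplasmic reticulum membrane proteins (0 and 3), oxidative phosphorylation (0 and 1), proteasome (0 and 2), cell wall and secreted proteins (0 and 1) and short-lived or degron-studied proteins (0 and 1) all fell, with the same counts over each list alone. No list had an adjusted p under 0.594 in limma's camera (0.754 with an estimated correlation). By fry 6 lists fell (adjusted p 0.000659 to 0.00279), of which glycolysis lost the call with TMM (0.0531). The median of nucleolar ribosome biogenesis was 1.04 while fry gave its direction as down (adjusted p 0.0668).

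More hydrophobic tails had lower slopes in the doa10 arm, with rho of -0.158 (-0.251 to -0.0720) for mean hydropathy, -0.120 (-0.213 to -0.0136) for the most hydrophobic 9 residues and 0.131 for acidic residues. Only reporter frame 1 had intervals below 0: mean hydropathy had 0.0289, -0.267 and -0.0374 in frames 0, 1 and 2, and the 9 residues had 0.145, -0.223 and -0.0847. The intervals in frames 0 and 2 span 0. Tails under 5 residues rose in 24.1% of 87 cases and tails of 20 or more in 11.6% of 276, a difference of -12.5 points (-21.9 to -3.86). That difference was 5.88 points in reporter frame 0, -9.60 points (-30.1 to 7.23) in frame 2 and -7.37 points (-20.6 to 5.42) with a minimum of 50 reads. Rising tails differed from other tails by -3.85 points in leucine (-5.68 to -1.97), 2.82 points in lysine (0.444 to 5.26) and 2.61 points in arginine (0.196 to 5.18). Glycine (-2.52, -3.75 to -1.05), glutamine (2.14, 0.293 to 4.38) and tryptophan (-0.862, -1.46 to -0.174) also differed. In each arm all residues were examined, without adjustment and not within a frame. Frame 0 tails start with GS and the others with R, so these differences cannot be told apart from the mix of frames.

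The nuclear and cytosolic arms were compared by the difference of slopes, which asks whether a tail acts differently with the nuclear reporter. The RIB3 fragment rose in the nuclear arm and fell by 4.31 ± 1.24 in the cytosolic arm, a difference of 7.30 ± 1.19, and native-frame NSR1, from the gene of a nucleolar protein, differed by 6.11 ± 1.35. A native-frame fragment of ASN1 (YPR145W, asparagine synthetase, chromosome 16, 824291 to 824551, 2.42 ± 0.47 in the cytosolic arm and -3.75 ± 0.92 in the nuclear arm) went the other way. So did SUB2 (YDL084W, an RNA export helicase gene, chromosome 4, 306551 to 307007, 2.04 ± 0.75 and -4.09 ± 0.99) and HTZ1 (3.27 ± 0.60 and -3.34 ± 0.75). Of 16940 fragments tested, 713 had the higher slope in the nuclear arm and 460 in the cytosolic arm, and the median difference was -0.11. An RPS8A difference of -5.42 ± 1.44 and an RPL12A difference of -3.06 ± 0.97 were among the lower ones. The difference was tested by edgeR as the interaction of arm and time. The split was 583 higher and 479 lower with TMM (median difference -0.41), 771 and 742 with size factors (-0.36) and 795 and 1998 with DESeq2 (-0.95). Without the cytosolic 12 h library it was 447 and 301, without cytosolic 48 h 325 and 309 and without cytosolic 72 h 45 and 101. It was 273 and 420 without nuclear 0 h, 300 and 372 without nuclear 12 h, 385 and 244 without nuclear 72 h, and 1046 and 613 without the nuclear 24 h library. A block per time point left 33 higher and 17 lower by edgeR (2101 and 1165 at an unadjusted p under 0.05). Of the named differences it kept the call of 3 (AIM7, HTZ1 and ASN1), and 30 others, RIB3, NSR1 and SUB2 among them, lost it with their direction unchanged. With no filter on low counts edgeR called 0 in each direction (2532 and 2113 at an unadjusted p under 0.05, 795 and 1998 by DESeq2 with the filter).

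The largest positive differences by the rule were those of RAP1 (8.39 ± 1.89), PTK2 (YJR059W, 7.71 ± 1.31), LEU5 (YHR002W, 7.64 ± 1.78), HST1 (YOL068C, 7.50 ± 1.28) and ATG4 (YNL223W, 7.44 ± 1.34). RIB3 was next, with ESC1 (7.21 ± 2.13), DBP3 (YGL078C, 7.19 ± 1.49), GAS5 (YOL030W, 7.19 ± 1.66) and AIM7 (YDR063W, 7.14 ± 1.22). The largest negative ones were those of the minus strand of chromosome 15 from 981102 to 981385 (-8.57 ± 1.62), CFF1 (YML079W, -8.55 ± 1.25) and MIX17 (YMR002W, -8.41 ± 1.26). Next were the minus strand of chromosome 2 from 483647 to 483908 (-8.36 ± 1.63), MRPL20 (YKR085C, -8.26 ± 1.21) and YML003W (-7.74 ± 1.78). The last were ARG1 (YOL058W, antisense, -7.70 ± 1.45), ERO1 (-7.70 ± 2.17), the unresolved insert on chromosome 4 from 512125 to 512128 (-7.58 ± 1.56) and ECM14 (YHR132C, -7.46 ± 1.70). Many of these rest on few reads in an arm: 477 of the 713 higher fragments had under 100 nuclear reads and 317 of the 460 lower ones under 100 cytosolic reads. Among 5080 fragments with at least 10 reads per library in each arm, 508 were higher and 252 lower. Most of the higher ones with a resolved insert were in reporter frame 0, with 368 higher and 37 lower of 1961 (median difference 1.24). Frame 1 gave 85 and 136 of 1834 (-0.30), and frame 2 gave 29 and 77 of 1239 (0.05). The slope difference had rho 0.143 (0.108 to 0.178) with the most hydrophobic 9 residues, 0.126 with tail length and -0.0926 with acidic residues. With 1 fragment per gene the interval reached 0 for the 9 residues (0.0368, -0.0198 to 0.0962) and for length (0.0523, -0.00137 to 0.106). Of 5080 fragments tested in both arms, 22 rose in both where independent lists would give 9.31 (Fisher's exact test, two-sided p = 0.00018). With resolved, unique inserts and no near-duplicates it was 20 against 9.56, and 21 against 11.5 without the nuclear 24 h library (p = 0.00683 by the same Fisher's exact test). Of the reporter frames, frame 1 alone passed (11 against 2.92, Fisher's exact test, two-sided p = 7.95e-05), while frame 0 gave 3 against 3.06 and frame 2 gave 6 against 2.99.

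The doa10 and cytosolic arms were compared in the same way, to ask which tails change their effect when the ligase is missing. Slopes are relative to the pool, and the pools differed at 0 h. There 63.0% of doa10 reads and 4.23% of cytosolic reads lay on fragments that rose in the cytosolic arm. The differences therefore cannot tell a changed effect of a tail from unlike starting pools or flasks. The IDP1 fragment with the tail RDPL rose in the cytosolic arm and fell in the doa10 arm, a difference of -7.42 ± 0.83. The same held for HTZ1 (-6.58 ± 1.07), for antisense EFM1 (YHL039W, a methyltransferase gene, chromosome 8, 21959 to 22917, -6.52 ± 1.05) and for the minus strand of chromosome 15 from 220336 to 220509 (-7.02 ± 0.83). RPS8A differed by -2.81 ± 0.46 and RPL12A by -2.70 ± 0.45. In the other direction stood ARO8 (3.62 ± 0.69), YDR524W-C (3.93 ± 0.66) and RPL13A (3.45 ± 0.59), which rose in the doa10 arm. Of 8532 fragments tested, 672 were higher in the doa10 arm and 222 lower, with a median difference of 2.11. The edgeR test gave the IDP1 difference an adjusted p of 2.26e-15. The split was 133 higher and 71 lower with TMM (median difference 1.39), 1706 and 110 with size factors (3.89) and 5310 and 125 with DESeq2 (4.45). It was 265 and 126 without the cytosolic 12 h library, 59 and 140 without cytosolic 72 h, and 346, 437 and 390 higher without the doa10 libraries of 0, 78 and 90 h. With doa10 times up to 72 h it was 35 and 116.

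The other large negative differences were those of DUG1 (YFR044C, -6.66 ± 1.30), MBF1 (YOR298C-A, -6.04 ± 1.10), and ENA2 (uncertain, -6.03 ± 0.87). Those of TEF2 (YBR118W, -5.81 ± 1.34), RPL19A (YBR084C-A, -5.79 ± 1.58, but 0.39 without doa10 0 h and 0.19 with DESeq2) and EFR3 (YMR212C, -5.65 ± 1.29) followed. The largest positive differences by the rule, such as ERT1 (YBR239C, 12.06 ± 1.92), MIX23 (YBL107C, 11.91 ± 1.70), RIB5 (YBR256C, 11.61 ± 1.88) and copies of a Ty element (YGR161C-D, 11.59 ± 1.89, split uncertain), rest on reads in 1 or 2 late doa10 libraries. Of the 672 higher fragments, 652 had under 100 doa10 reads and 641 had at most 2 at 0 h. Among 511 fragments with at least 10 reads per library in each arm, 19 were higher and 218 lower. The slope difference had rho -0.137 (-0.261 to -0.00950) with the most hydrophobic 9 residues and 0.0521 (-0.0389 to 0.136) with tail length. For the 9 residues the interval reached 0 with 1 fragment per gene (-0.109, -0.236 to 0.0293) and in frames 0 and 2, and mean hydropathy had -0.0151 (-0.114 to 0.0907).

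The ratio of the 72 h to the 0 h share, the times that all arms have, was above 1 for 8.58% of tested fragments in the cytosolic arm (95% interval 8.06 to 9.12), 17.0% (16.4 to 17.6) in the nuclear arm and 24.0% (20.7 to 27.5) in the doa10 arm. These ratios add 1 read to each count. With a pseudocount of 10 reads the values were 46.4%, 21.2% and 27.1%, and with TMM 31.02%, 27.9% and 35.9%. The order of the arms turned, but the same number of reads was added to libraries of unlike totals. A fragment with 0 reads at 72 h can therefore count as higher. The median log2 ratio was -3.19, -4.04 and -4.17. At 72 h 8260 of 10796 cytosolic, 7620 of 14035 nuclear and 267 of 605 doa10 fragments had 0 reads. The percentages thus depend on the pseudocount and cannot rank the arms, and the values have no test.

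**Figure D3:**
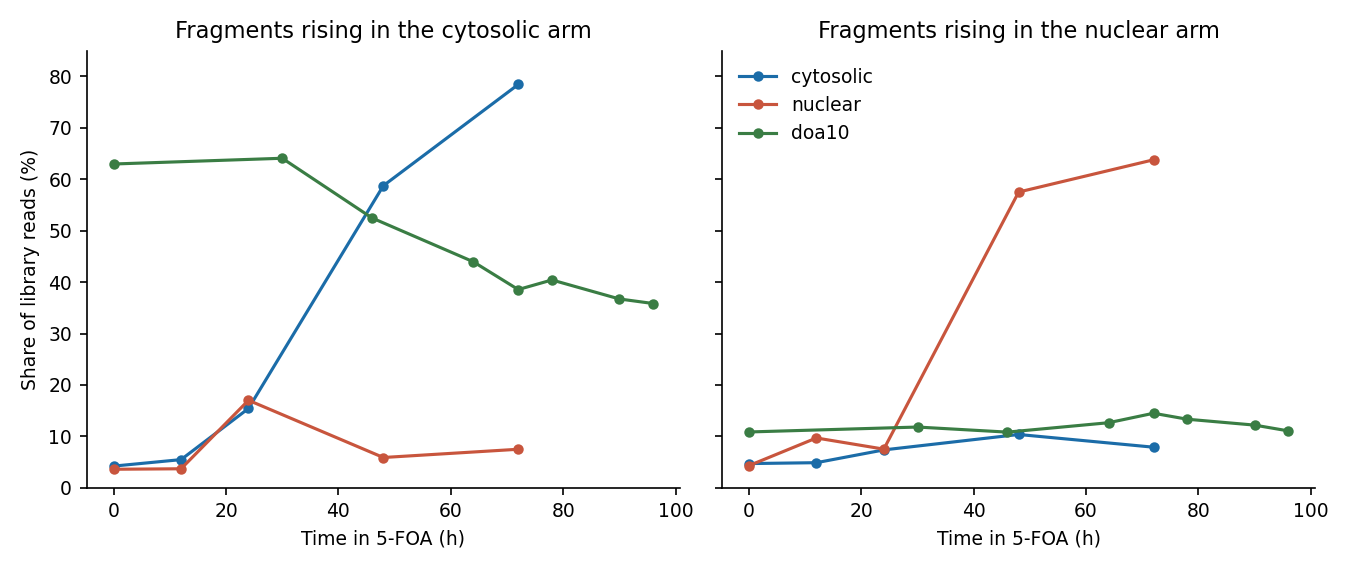
Share of library reads (percent) against time in 5-fluoroorotic acid (h) on the fragments that rose in the cytosolic arm (left) and in the nuclear arm (right), with 1 line per arm and 1 point per library. The cytosolic risers climb from 4.23% to 78.4% in the cytosolic arm and go from 63.0% to 35.8% in the doa10 arm, and the nuclear 24 h library stands out with 17.0%.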

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

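The contrast of long and near-empty tails, the pairs of reading frames, the draws and mixture for the nuclear 24 h library, the share of the doa10 0 h library and all reorderings and splits of libraries were chosen after the result was seen, and the other tests were written down first.

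The tests of a difference between arms gave 713 fragments higher and 460 lower in the nuclear than in the cytosolic arm, with RIB3 at 7.30 ± 1.19 and ASN1 at -6.15 ± 1.02. Without single libraries the lowest counts were 45 and 101 (without cytosolic 72 h) and the highest 1046 and 613 (without nuclear 24 h), and a block per time point left 33 and 17. Of 100 splits of the 10 libraries between the arms, 7 gave at least the real 1173 calls, and the highest other gave 5551. Chance is therefore not excluded for this count. What gave another split several times the real count was not tested. The slope difference also had a rho of 0.143 with the most hydrophobic 9 residues of the tail, but 0.0368 (95% interval -0.0198 to 0.0962) with 1 fragment per gene. In the doa10 arm 672 fragments were higher and 222 lower than in the cytosolic arm, with IDP1 at -7.42 ± 0.83, and the rho with the most hydrophobic 9 residues was -0.137, or -0.109 (-0.236 to 0.0293) with 1 fragment per gene. Without cytosolic 72 h these counts were 59 and 140. At least the real 894 calls came from 2 of 100 splits, the real one included, and the highest other gave 957, a share under 0.05. The splits mix libraries of arms with unlike times and unlike pools at 0 h. This share therefore cannot tell a difference of slopes from one of pools or flasks. Of the 672 higher fragments, however, 652 had under 100 doa10 reads and 641 had at most 2 at 0 h. With at least 10 reads per library in each arm 19 were higher and 218 lower, and the median difference was -1.62. For the trends, the real order of times alone gave the most calls. It was 1 of 60 orders in the cytosolic arm (7284 calls, highest other 5474) and 1 of 60 in the nuclear arm (10347, highest other 9378). In the doa10 arm it was 1 of 100 (453, highest other 305). A chance order of the time labels is thus argued against for the total of calls. Any gradual change within a single flask, whatever its cause, would also favour the real order. Reordering therefore cannot exclude chance change in that flask. For rises alone, at least the real 74 of the doa10 arm came from 2 of 100 orders, the real one included, and the highest other gave 166. The doa10 orders were drawn without limits, and this share is under 0.05. All 60 orders of the other arms gave the 0 h library an earlier time than the 72 h library. Orders that could turn falls into rises were thus left out. The highest other order gave 249 rises against 288 in the cytosolic arm and 549 against 858 in the nuclear arm. For that reason these counts cannot exclude chance for rises.

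Rises in the cytosolic arm hardly followed tail length, though the rho of the slope with length was 0.0236, or 0.0843 (0.0474 to 0.119) with 1 fragment per gene. RPS8A with at least 116 residues and IDP1 with 4 both rose, and long tails exceeded near-empty ones by 0.379 points. The excess was 0.780 points (95% interval 0.0123 to 1.55) without near-duplicates and -3.07 points (-6.70 to -0.285) in the p columns. Other features did vary, as tails ending in proline rose in 7.53% of cases and those ending in arginine in 0.784%. The slope had a rho of 0.112 with acidic residues, whose share depends in part on the reporter frame and was not examined within a frame. Low read totals of the late cytosolic libraries, taken alone, are argued against. The nuclear arm thinned to those totals kept an excess of 5.08 points (95% interval 3.94 to 6.09). The thinning matched totals only, not how reads were spread over fragments. At 72 h the 10 leading fragments held 39.1% of reads in the cytosolic arm and 9.65% in the nuclear arm. Few reads left for the other cytosolic fragments therefore remained open as a cause. Cells that lost reporter function without help from the tail remained open, since the small excess is the pattern itself and lends no support of its own. Effects of the insert itself, whatever its reading frame, remained open. Pairs of frames of the same insert rose together in 9 cases where 2.502 are expected (exact Poisson test, two-sided p = 0.0023), but some of these pairs have few reads in 1 frame beside many in the other. Among pairs with reads within 10 times there were 4 against 1.49 expected, a ratio of 2.68 (95% interval 0.729 to 6.85), too few to decide. A biological difference between the reporters remained open and untested, as the arms are single flasks.

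The nuclear 24 h library, with 9063 reads, had 17.0% of reads (16.3 to 17.8) on fragments that rose in the cytosolic arm. Low depth is argued against, as the highest of 1000 draws of that size from the nuclear 12 h and 48 h libraries was 6.69%, and a state of the culture is argued against by 4.77% in the p column of that time. Reads of cytosolic libraries in this library are a candidate explanation: as a weighted sum of read shares it had a cytosolic weight of 84.6%, against 0.537% for nuclear 0 h, 0.666% for nuclear 72 h and 5.39% for the p column. A first bound of 5% for the p column was dropped after that value was seen. Fragments with cytosolic reads and almost none in other nuclear libraries held 6.48% of its reads, between the bounds written down for that test (at least 10% or under 1%). That test therefore did not decide. The mixture was chosen after the result was seen, so cytosolic reads remain a candidate only.

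The doa10 pool at 0 h resembled the selected cytosolic pool, with RPS8A at 9.08% of reads and RPL12A at 7.83%. Low depth is argued against: cytosolic 0 h thinned to the same depth had 2.84% of reads on its 10 leading fragments, against 35.6%. Of its reads 63.0% lay on fragments that rose in the cytosolic arm, against 4.23% in cytosolic 0 h and 78.4% in cytosolic 72 h. This share restates the pattern, so cells that had already been under selection remained open. Loss of DOA10 as a cause remained open, because the deletion and the flask cannot be separated by design.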

How the results depend on the processing

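The p columns, single reporter frames, the minimum in each arm, a block per time point, unique resolved inserts and the omission of near-duplicates were added after the data were seen, and the other settings were planned. Under the alternatives, 111 counts of calls lay within 1.5 times the reported count and 81 did not. In camera the gene lists kept their side of the threshold in 102 cases and passed it in 1. Named fragments and tail contrasts kept their side of the threshold in 2809 cases, lost the call in 545, gained it in 23 and turned in 12. Where called, the 2809 also kept their direction, but a value called in neither setting may have changed it. In another 8 cases a value without a call as reported turned and was called. With TMM, 238 fragments fell in the cytosolic arm, 1624 rose and 6230 fell in the nuclear arm, and doa10 against cytosolic gave 133 higher and 71 lower. Size factors gave 624 rises in the cytosolic and 1336 in the nuclear arm, 742 lower for nuclear against cytosolic, and 1706 higher and 110 lower for doa10 against cytosolic. DESeq2 gave 700 cytosolic rises, 1440 nuclear rises and 5435 falls, 129 doa10 rises, 1998 lower for nuclear against cytosolic, and 5310 higher and 125 lower for doa10 against cytosolic. DESeq2 changes the test as well as the scaling. Without a filter on low counts there were 1076 rises and 4081 falls in the cytosolic arm, 291 and 818 in the doa10 arm, 0 and 0 calls by edgeR for nuclear against cytosolic (2532 and 2113 at an unadjusted p under 0.05; DESeq2 with the filter 795 and 1998) and 312 and 477 for doa10 against cytosolic. A minimum of 50 reads, which tests fewer fragments, left 189 cytosolic rises, 516 rises and 5536 falls in the nuclear arm and 32 and 210 in the doa10 arm. With the rank of time there were 88 rises and 237 falls in the cytosolic arm, 21 rises in the doa10 arm, 240 and 256 for nuclear against cytosolic and 134 higher for doa10 against cytosolic. Times up to 72 h, which leave fewer libraries, gave 0 and 0 calls by edgeR in the doa10 arm (63 and 266 at an unadjusted p under 0.05; DESeq2 over all times 129 and 289) and 35 and 116 for the difference. A joint fit gave 247 higher for doa10 against cytosolic. The p columns, which are shallower, gave 136 and 3199 in the cytosolic arm, 440 and 3775 in the nuclear arm, 114 and 137 in the doa10 arm, and 428 and 125, and 27 and 91, for the differences. A minimum in each arm gave 252 lower for nuclear against cytosolic and 19 higher for doa10 against cytosolic.

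Leaving out each library in turn gave 10 to 276 rises and 0 to 7029 falls in the cytosolic arm, 144 to 900 and 6894 to 9976 in the nuclear arm, and 16 to 82 and 202 to 390 in the doa10 arm. For nuclear against cytosolic it gave 45 to 1046 higher and 101 to 613 lower, and for doa10 against cytosolic 59 to 791 higher and 126 to 221 lower. The lowest cytosolic counts, 10 and 0 by edgeR (380 and 3879 at an unadjusted p under 0.05; DESeq2 with all libraries 700 and 4761), came without 72 h. The other libraries that moved a count by more than 1.5 times stand beside the counts in the report.

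In the cytosolic arm, rho with tail length turned to -0.0182 in frame 0, -0.0231 in frame 2 and -0.00519 for the 72 h over 0 h ratio. The correlation with hydropathy turned to 0.00789 with a minimum of 50 reads, 0.0276 in frame 0 and 0.0851 in frame 2, and its interval reached 0 with 1 fragment per gene (-0.0185), in frame 1 (-0.0100) and for the ratio (-0.0127). The correlation with the most hydrophobic 9 residues turned to -0.0225 in frame 1 and reached 0 in frame 0 (0.0355) and for the ratio (0.0170). In the doa10 arm, rho with length was 0.120 without tails under 5 residues, rho with hydropathy 0.0289 in frame 0 and -0.0374 in frame 2, and rho with the most hydrophobic 9 residues 0.145 in frame 0 and -0.0847 in frame 2. For nuclear against cytosolic, the interval reached 0 with 1 fragment per gene, at 0.0523 with length and 0.0368 with the most hydrophobic 9 residues. For doa10 against cytosolic the latter reached 0 and was -0.109 with 1 fragment per gene, -0.138 in frame 0 and -0.109 in frame 2. The cause was not tested. Glycolysis in the nuclear arm passed in camera with TMM, at a median of -0.10 (adjusted p 0.00247; 0.00247 to 0.997 over its alternatives, 0.338 as reported), a call lost with an estimated correlation (0.970). In fry, TMM lost 9 of 12 calls in the nuclear and 2 of 12 in the cytosolic arm. Native-frame fragments gave no value in the doa10 arm for oxidative phosphorylation, proteasome, histones, cell wall and short-lived proteins. The percent of fragments higher at 72 h than at 0 h was 31.02 in the cytosolic arm with TMM and 46.4 with a pseudocount of 10 reads. With 48 h as the end it was 12.1 there. In the nuclear arm it was 27.9 with TMM and 21.2 with that pseudocount, and in the doa10 arm 35.9 and 27.1. A fragment with 0 reads at the end can count as higher through the pseudocount, so these percents are not read shares that rose.

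The excess of long tails turned to -3.07 points in the cytosolic arm in the p columns and to 5.88 points in the doa10 arm in frame 0. In the cytosolic arm it was 0.150 points with TMM and 0.835 with DESeq2. The plus strand of chromosome 4 from 130300 to 130417 turned to -0.60 and FBA1 to -1.42 in the cytosolic arm of the p columns. In the doa10 arm RPL12A turned to 0.40 with TMM, 0.18 with median-of-ratios size factors and 0.18 with DESeq2, and RPL1B to 0.22, 0.00443 and 0.00437. The RPL19A difference between doa10 and cytosolic turned to 0.19 with DESeq2 and ran from -6.17 to 0.39 without single libraries, the latter without doa10 0 h. The cause was not tested. Depth was lowest in the nuclear 24 h library (9063 reads). In simulated data with few fragments changed, a slope of 2 log2 units per day was called for 39.4% of them in the cytosolic arm. In the nuclear arm it was called for 25.8%. No paired analysis by replicate number was possible because every number is 1. The times that the nuclear and cytosolic arms share allow a block per time point, which leaves fewer residual degrees of freedom and gave 33 higher and 17 lower for nuclear against cytosolic by edgeR (2101 and 1165 at an unadjusted p under 0.05).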

Other observations

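The comparison of fragments by their fate, the residue shares at the tail end and the pairs of reading frames were examined only after the trends were seen.

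RPL16B in another frame rose in the cytosolic arm (3.38 ± 0.51) and had a slope of 1.07 ± 0.43 in the nuclear arm, and antisense RRN5 rose in the nuclear arm (3.05 ± 0.56) and had 0.78 ± 0.25 in the doa10 arm. Of 162 fragments that rose in the cytosolic arm and were tested in the nuclear arm, 22 rose and 88 fell there. The falls were 54.3% of them, against 59.2% of the 3118 fragments that fell in the cytosolic arm. The most abundant insert at 0 h, on chromosome 4 from 130300 to 130417, rose on its plus strand in the cytosolic arm (0.62 ± 0.18) and fell in the doa10 arm (-1.76 ± 0.32).

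Cytosolic tails ending in proline rose in 7.53% of 332 cases (95% interval 4.76 to 10.4), those ending in alanine in 5.11% of 235 and those ending in arginine in 0.784% of 638. Among fragments with a resolved insert and without near-duplicates that rose in the cytosolic arm and were tested in the doa10 arm, the 66 that fell in the doa10 arm, IDP1 and HTZ1 among them, had tails of 17.4 ± 15.1 residues (mean and SD), and the 44 others had 30.0 ± 27.3 (permutation test, two-sided p = 0.00181, adjusted 0.00543 over 3 features). By the same permutation test, mean hydropathy (p = 0.803) and the most hydrophobic 9 residues (p = 0.418) did not pass. The same insert in different reporter frames had slopes with rho 0.188 to 0.278 in the cytosolic arm and 0.115 to 0.231 in the nuclear arm, across inserts, which are not independent replicates. Of the 100 leading fragments, 54 were shared by doa10 0 h and cytosolic 48 h, and 20 by doa10 0 h and cytosolic 0 h.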
